A study of Drosophila melanogaster with 7 samples.

How the data were processed

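The libraries were Nanopore sequencing libraries of genomic DNA from Drosophila S2 cells, described in the labels by treatment, labelling times and replicate number. Per the submitters' processing notes, minimap2 2.24, SAMtools 1.10 and the dm6 build were among the tools used. Per the file headers, forks, origins and terminations were called by the forkSense step of DNAscent 4.0.1 or 4.0.3, a neural network caller for thymidine analogues, with the analogue order EdU then BrdU. The file of a library joined the output of several sequencing output blocks, from 2 in the control to 14 in the 7 and 15 min replicate 1. Version 4.0.3 made 13.8% of the forks of that replicate, 9.43% of those of replicate 2 and 100% of those of the 3 and 6 min replicates. Base calling settings are not given in the sources used here.

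The deposited fork files gave, for each fork, the coordinates of track and read, the lengths in bp of the track, its EdU segment and its BrdU segment (other values), 4 fractions and a stall score. The deposited fractions are shares of thymidine positions called per analogue, which analogue each one counts is not given in the file, and they were not used in any comparison. The stall score of the authors runs from 0 to 1, and codes below 0 mark forks without a score. The most frequent code, -3, marked forks whose BrdU end lay 0.884 ± 0.579 kb from the read end (median per library, SD, n = 5), against 17.1 ± 2.27 kb for scored forks. Origin and termination files gave coordinates, with zero width where segments met. In the 7 and 15 min replicate 2, 45 origins lay on reads with no fork in the fork files. The gradient file gave origin coordinates and read names without read coordinates. No read with a fork was shared between libraries (0 reads).

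Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Calls on the arms 2L, 2R, 3L, 3R, 4 and X entered. A complete fork ended at least 5 kb inside its read at both ends and lay over 1 kb from any origin or termination on that read. This left 660 complete forks in the control, 3504 and 3997 in the 7 and 15 min replicates 1 and 2, 292 and 752 in the 3 and 6 min replicates 3 and 4, and 6 with HU, where all 24 forks on the arms were therefore compared with all 1836 of the control. A track was leading-strand where a forward read held a rightward fork or a reverse read a leftward fork. Rates are median lengths divided by labelling time. Genes came from a RefSeq gene table of assembly Release 6 plus ISO1 MT, the same release as dm6, with 13922 protein-coding genes on the main arms. It holds gene spans without strand or exons.

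Groups came from the titles in the labels. The choice of tests, the comparisons and most alternatives were fixed before the data were examined. Comparisons of schemes used exact two-sided permutation of 2 against 2 libraries, whose smallest p is 0.333. Values paired within libraries used exact two-sided sign-flip tests over 5 libraries, whose smallest p is 0.0625. Strand classes were permuted within libraries 100000 times and libraries were weighted equally. Positions were tested by placing each call 10000 times at random on its own read, which keeps coverage and read length and is called a permutation of positions, tile recurrence by 1000 placements, and gene density by permuting window labels within arms. Log2 ratios of origin rates by gene density and between X and autosomes were taken with 0.5 added to each origin count. All were two-sided. HU was set beside the control with percentile intervals from 10000 bootstrap draws of forks, at 95%. Shares carry Wilson or exact intervals that cover counting error only, and the limit for a count of 0 is 3 counts. Origins per 100 forks rest on 97 to 683 origins per library. The label permutation was tested on simulated data of 9205 forks: it called 5% of 40 runs with no effect and 100% of runs with a log2 effect of 0.1. The placement test on 1512 simulated origins called 5% of 40 runs with no effect and 97.5% of runs in which a share of 0.1 of the origins was moved to gene ends. Simulated origins were first placed in the same way as the random ones. These runs therefore check the calculation, and not whether uniform placement on a read suits real origin calls.

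Named regions followed a rule fixed before the data were examined: the 20 tiles of 10 kb with origins of most libraries, the 5 with stalled fork ends of most libraries, the 5 with terminations of most libraries, each with the protein-coding gene that holds or is nearest to the mean midpoint, and up to 4 members of each gene list with a raw p under 0.05. Members of other lists are named where a list held few origins and were chosen after their values were seen. The 13 gene lists were ribosomal proteins, histones, Hox, hemocyte and S2 genes, housekeeping, neuronal, germline and testis, chorion, heat shock, replication factors, long genes, tRNA genes, and snRNA and snoRNA genes. Their members were matched by symbol or gene type in the gene table. Counts are pooled over libraries, as the lists are small.

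Comparisons of forks moving with or against transcription (length, stall share and share of forks), GC content at origins, and origin classes by transcription start, 3′ end, exon and intron were planned and not run, since strand, exons and genome sequence were not used here. The intergenic class was kept as planned and a gene-end class, set after the columns of the gene table were seen, took the place of the other origin classes, which changed the Benjamini-Hochberg adjustment to 2 classes. Forks on the mitochondrial chromosome and on unplaced sequences were left out. EdU and BrdU segment files were counted only. The alternatives changed the filter on read ends, read length, segment, summary, stall threshold, window, distance, random placement, margin, library weights and library set.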

Results

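Replication was followed on single DNA molecules of S2 cells, a line derived from Drosophila melanogaster embryos, by Nanopore sequencing of DNA labelled with thymidine analogues. Cells received EdU and then BrdU, each at 10 µM, and a chase of 20 min in 50 µM thymidine, so that each moving fork left an EdU segment followed by a BrdU segment. The series held 7 libraries. An untreated control and a library with 1 mM HU in the BrdU medium were labelled for 7 min and 15 min. HU is the usual abbreviation of hydroxyurea, an inhibitor of ribonucleotide reductase, although the labels give only the abbreviation. Replicates 1 and 2 were also labelled for 7 and 15 min, and replicates 3 and 4 for 3 and 6 min. In the last library BrdU was raised by 0.5 µM every 2.5 min up to 12 µM over 1 hr, with a final 30 min, and only origin calls from it were analysed here.

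The 5 untreated pulse libraries held 30828 fork calls on 27297 reads, 1513 origin calls and 1984 termination calls. Fork calls numbered 1853 in the control, 10390 and 12814 in the 7 and 15 min replicates 1 and 2, and 3035 and 2736 in the 3 and 6 min replicates 3 and 4. Origin calls numbered 97, 485, 683, 110 and 138 in the same order. The HU library held 26 forks and no origin, and the gradient library held 1529 origin calls on 1028 reads. Median mapped lengths of reads with a fork were 55.4 kb in the control, 22.7 kb with HU, 53.1 and 55.0 kb in replicates 1 and 2, and 28.2 and 34.2 kb in replicates 3 and 4. The labels do not say that replicates were separate cultures. The p-values of tests over libraries therefore measure only the spread between these samples, which may be technical. Permutations of strand labels, sister partners or window labels, and placements of calls, use forks, pairs, windows or calls as units. Their p-values do not measure the spread between samples. All positions below are on dm6, counted from 1.

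The first question was how fast forks moved and whether the pulse length changed the answer. Complete forks, which ended at least 5 kb inside the read and lay over 1 kb from any origin or termination on it, had median tracks of 14.7 and 15.7 kb in the 7 and 15 min replicates 1 and 2. The medians were 11.9 and 8.83 kb in the 3 and 6 min replicates 3 and 4. Divided by the labelling time, the rate was 0.690 ± 0.0346 kb per min (SD, n = 2) with the long pulses and 1.15 ± 0.244 kb per min (SD, n = 2) with the short pulses. The control gave 0.643 kb per min. The rate was higher in both short-pulse libraries than in either long-pulse library, by 0.463 kb per min on average (exact two-sided permutation test of 2 against 2 libraries, p = 0.33, the smallest that this design allows). Without the 3 and 6 min replicate 3, where only 9.74% of forks were complete and BrdU ends lay a median of 1.31 kb from the read end, the difference was 0.290 kb per min. Batch and pulse scheme coincide in the labels and cannot be told apart, and the caller version differed too: replicates 3 and 4 were called wholly with DNAscent 4.0.3, most forks of replicates 1 and 2 with 4.0.1. With forks of version 4.0.3 alone in every library, a setting chosen after the data were seen, the difference was 0.566 kb per min. The rates themselves depended on the filter on read ends and on read length. Over all called forks they were 0.649 kb per min with the long and 0.958 kb per min with the short pulses. With both ends at least 10 kb inside the read they were 0.794 and 1.23 kb per min. On reads of 100 kb or more they were 0.914 and 1.34 kb per min, so no single absolute rate follows.

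**Figure D1:**
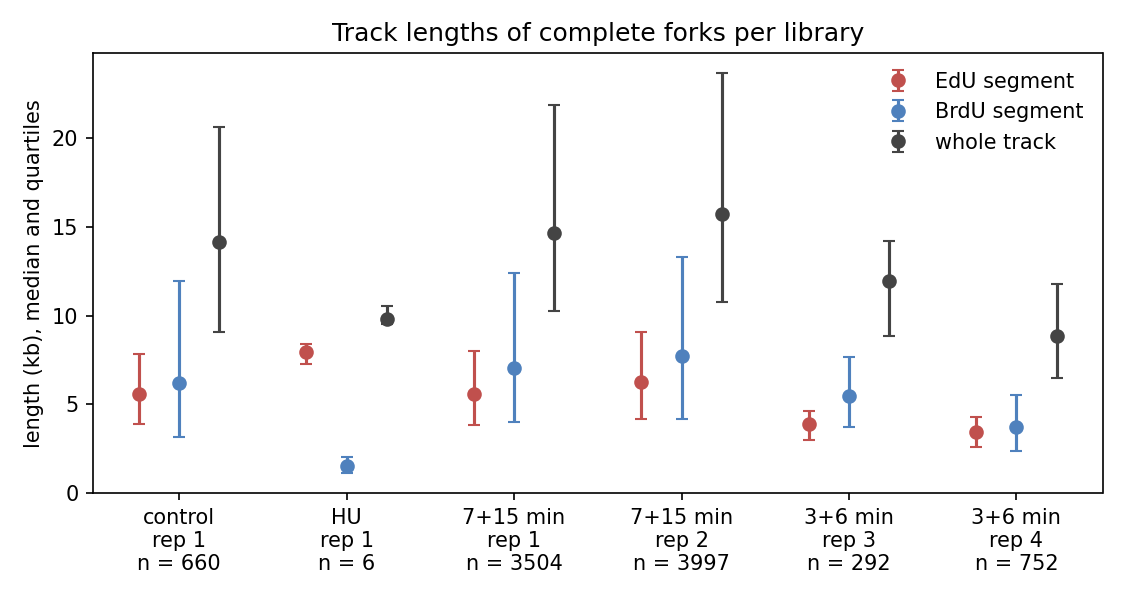
Median length in kb of EdU segments, BrdU segments and whole tracks of complete forks in each library with pulses, with bars from the lower to the upper quartile and the number of forks under each library. Whole tracks have medians of 14.7 and 15.7 kb in the 7 and 15 min replicates and 11.9 and 8.83 kb in the 3 and 6 min replicates, and BrdU segments of the 6 complete forks with HU have a median of 1.55 kb.

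Within single forks, called BrdU segments were shorter per minute of labelling than EdU segments. The median fork had a BrdU length per minute of 0.593 times its EdU length per minute as mean over the untreated libraries, a log2 ratio of -0.75 ± 0.16 (SD, n = 5 libraries; exact sign-flip test, p = 0.062, the smallest that 5 libraries allow). The direction was the same in 5 of 5 libraries, and the log2 ratio was -0.65 with both ends at least 10 kb inside the read and -0.63 on reads of 100 kb or more. Whether slower synthesis, the calling of segments or analogue carried over between pulses made the difference was not tested. EdU segments measured 0.849 ± 0.0662 kb per min (SD, n = 2) and BrdU segments 0.492 ± 0.0316 kb per min (SD, n = 2) with the long pulses, against 1.23 ± 0.105 and 0.770 ± 0.208 kb per min (SD, n = 2) with the short ones. Leftward forks made up between 49.1% and 51.3% of the forks of an untreated library. Their tracks were 0.346 ± 0.284 kb longer than those of rightward forks (SD, n = 5 libraries; exact sign-flip test, p = 0.125), a difference not past the threshold that turned to -0.160 kb when forks had to end 10 kb inside the read and to -0.581 kb on reads of 100 kb or more.

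HU was present only in the BrdU medium, after the EdU pulse. BrdU segments were short with HU, with a median of 2.17 kb (95% interval 1.22 to 2.79 kb) over 24 forks, against 6.05 kb (5.77 to 6.43 kb) over 1836 forks in the control. EdU segments were longer with HU, at 8.26 kb (5.78 to 8.62 kb) against 5.30 kb (5.12 to 5.49 kb), so the forks called in these libraries already differed in the segment labelled first, for a reason that was not tested. The length ratio of BrdU to EdU was 0.272 (0.134 to 0.386) with HU and 1.16 (1.1 to 1.23) in the control, and the BrdU segment was the shorter one in 79.2% of the forks with HU and 42.2% of those in the control. Because of the difference in EdU segments, this ratio compares unlike forks and does not measure the effect of the drug alone. Whole tracks measured 10.7 kb with HU and 13.8 kb in the control. Of 9 scored forks with HU, 3 had a stall score of at least 0.5, which is 33.3% (exact 95% interval 7.49 to 70.1%), and of 1002 in the control 259 had one, 25.8% (23.2 to 28.7%), so no difference in stalling was detectable at this depth. No origin was called with HU, where the control's rate would give 1.36, and 0 calls over 26 forks allow up to 11.5 origins per 100 forks. Against the 7 and 15 min replicates 1 and 2 in place of the control, the BrdU segment with HU was 0.350 times, the EdU segment 1.44 times and the whole track 0.743 times as long. HU had 1 library with no replicate, so no p-value is given, and the intervals cover only the sampling of forks. HU reads were short, and on reads of 50 kb or less, a setting chosen after the data were seen, the whole track was 0.973 times that of the control (0.900 to 1.08), while the BrdU segment was 0.479 times as long.

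The strand of each read and the direction of its fork tell whether the sequenced nascent strand was the leading or the lagging one. Lagging-strand tracks were longer than leading-strand tracks in 5 of 5 untreated libraries, with medians of 15.6 ± 3.85 kb and 12.1 ± 2.52 kb (SD, n = 5). The mean log2 ratio of leading over lagging length was -0.31 ± 0.15 (SD, n = 5; permutation of strand labels within libraries, p = 1e-05, the smallest it can give; exact sign-flip test over libraries, p = 0.062), which is a lagging track 1.24 times as long. Leading-strand molecules were the more frequent class, with 62.5% ± 5.99 of all forks and 72.7% ± 5.32 of complete forks (SD, n = 5; exact sign-flip test against 50%, p = 0.062 for each). Between the sister forks of one origin on one read, of which one is read as leading and the other as lagging, the difference was not seen: the mean log2 ratio over 494 pairs was 0.021 (95% interval over libraries -0.050 to 0.092; permutation of signs, p = 0.545). This pairing was chosen after the data were seen.

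**Figure D2:**
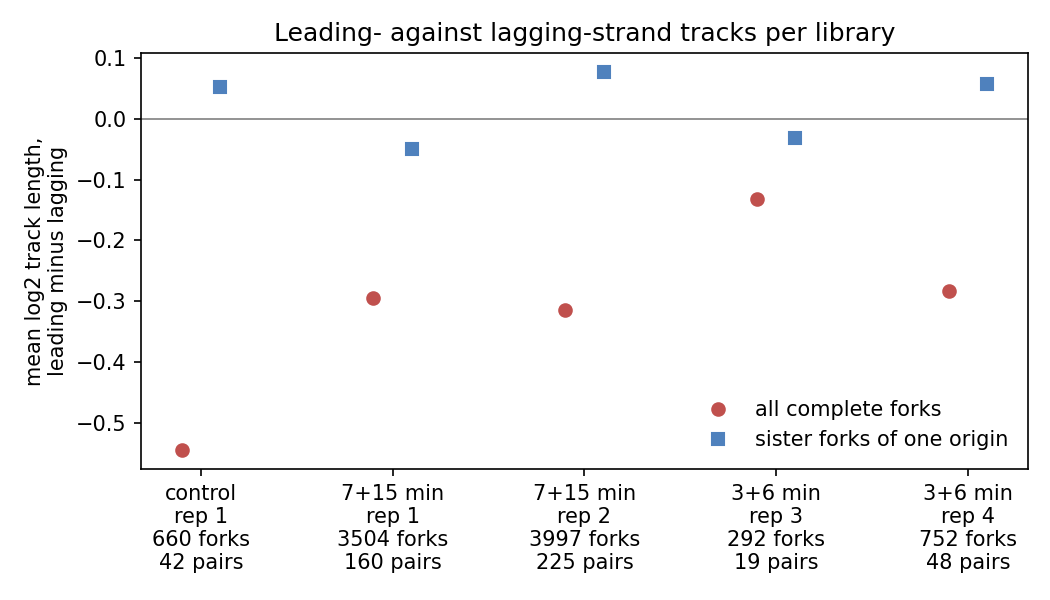
Mean log2 ratio of leading-strand over lagging-strand track length in each untreated library, for all complete forks (circles) and for sister forks of one origin on one read (squares), with the number of forks and of sister pairs under each library. All complete forks lie below 0 in 5 of 5 libraries and average -0.31, while sister forks lie on both sides of 0 and average 0.021.

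Forks with a stall score of at least 0.5 made up 25.7% ± 11.4 of scored forks (SD, n = 5), from 18.3% in the 3 and 6 min replicate 3 to 45.4% in replicate 4 of the same scheme. Only 39.8% ± 15.8 of forks carried a score (SD, n = 5), and in replicate 3 only 12.9% did. The stalled share was 27.5% of leading-strand forks and 22.7% of lagging-strand forks, a difference of 4.80 ± 5.20 percentage points (SD, n = 5; permutation of strand labels within libraries, p = 0.00011; exact sign-flip test over libraries, p = 0.188). Without the 3 and 6 min replicate 4 the difference was 3.17 percentage points (permutation p = 0.0169), with a threshold of 0.8 it was 2.39 points (permutation p = 0.00431), with 0.3 it was 6.41 points (permutation p = 1e-05) and with forks pooled over libraries 2.78 points (permutation p = 0.00023). The control gave 25.6% for leading and 26.2% for lagging forks, the only untreated library with the opposite order.

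Stalled fork ends recurred in a few 10 kb tiles. The tile with most libraries lay at 2R 14570001 to 14580000, where 4 untreated libraries had 1 stalled end each and their mean position, 14574285, fell inside LamC, a nuclear lamin gene, and inside ttv, which makes an enzyme of heparan sulfate synthesis. Stalled ends of 3 libraries met at 3L 560001 to 570000 inside Hipk, a protein kinase gene, and at 2R 1380001 to 1390000 inside l(2)41Ab. Tiles near CG2528 at 2L 21960001 to 21970000 and near CG32115 at 3L 12930001 to 12940000 also held stalled ends of 3 libraries. Of 2437 tiles with a stalled end, 2166 had it in 1 library, and no test of the recurrence of stalled ends was run.

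Origins were called at 5.04 per 100 forks with the long pulses and 4.36 with the short ones, a difference of -0.681 (exact permutation test of 2 against 2 libraries, p = 0.667). Single libraries ranged from 3.63 in the 3 and 6 min replicate 3 (95% Wilson interval 3.02 to 4.37) to 5.36 in the 7 and 15 min replicate 2 (4.98 to 5.76). In that replicate 45 of 683 origins lay on reads without a fork in the fork files. Without them, a setting chosen after the data were seen, its value was 5.01, below the 5.28 of the control, and the difference between schemes was -0.505 (exact permutation p = 1). Without the 3 and 6 min replicate 3 the difference was 0.0419, and without its partner replicate 4 it was -1.40. Per Mb of mapped read it was 0.344 in the other direction, with 1.26 origins per Mb in the short-pulse and 0.911 in the long-pulse libraries. On reads of 100 kb or more it was -2.16, with 7.80 origins per 100 forks in the short-pulse and 9.95 in the long-pulse libraries (exact permutation p = 1). Only 29 reads held more than 1 origin, with 30 distances between neighbours and a median of 37.5 kb (10.8 to 89.1 kb), a value that read length bounds. The forks that left one origin had correlated lengths: over 494 sister pairs, log2 track lengths correlated with Pearson r = 0.642 ± 0.0709 and Spearman rho = 0.632 ± 0.108 (SD, n = 5 libraries; permutation of partners within libraries, p = 1e-05, the smallest it can give). Pairs are molecules, not independent replicates. Sisters share a read, and called tracks were longer on reads of 100 kb or more. Partners were permuted without regard to read length, so the test does not separate read length from the forks themselves. BrdU segments alone, which cannot share a boundary at the origin, gave r = 0.397 in a setting chosen after the data were seen. Origins with a gap between their 2 EdU segments, also chosen then, gave r = 0.629 over 258 pairs.

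Origins lay near the ends of protein-coding genes more often than chance placement on the same molecules gave. Over the 5 untreated libraries 43.7% of origin midpoints lay within 1 kb of an end of a protein-coding gene, against 28.9% when each origin was placed at random on its own read (a permutation of positions), a difference of 14.8 ± 2.91 percentage points (SD over libraries). The excess ran from 12.1 points in the 3 and 6 min replicate 4 to 19.0 points in the control and was present in 5 of 5 libraries. Its p of 0.0001 was the smallest that 10000 placements can give (0.0002 after Benjamini-Hochberg adjustment over the gene-end and intergenic classes). Intergenic positions held 35.2% of origins against 31.6% at random, an excess of 3.60 ± 1.98 points in 5 of 5 libraries (SD over libraries; permutation p = 0.0035, adjusted permutation p = 0.0035). This class overlaps the gene-end class and is not a separate preference. Pooled over libraries, protein-coding genes with 1 kb on either side held 1159 origins against 1144 at random (permutation p = 0.238). With 5 kb they held 1328 against 1286, so no intergenic excess was seen beyond 1 kb from genes. Terminations showed no excess in either class. Of their midpoints 23.4% lay near gene ends against 25.1% at random (-1.67 ± 0.97 points, below random in 5 of 5 libraries, permutation p = 0.159, adjusted permutation p = 0.319), and 31.7% were intergenic against 32.2% (-0.427 ± 1.20 points, permutation p = 0.688, adjusted permutation p = 0.688). With calls pooled over libraries the termination difference near gene ends was -1.90 points with a raw permutation p of 0.0374. The gene table gives no strand, so an end is either end of a gene, and the gene-end class was set after its columns were seen. Origin calls had median widths of 12.4 kb in the control, 11.9 and 6.81 kb in the 7 and 15 min replicates 1 and 2, and 0 kb in both 3 and 6 min replicates. A midpoint therefore need not lie within 1 kb of the true origin. With calls up to 5 kb wide alone, 38.4% lay near gene ends against 26.8% at random, an excess of 11.7 points (permutation p = 0.0001).

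**Figure D3:**
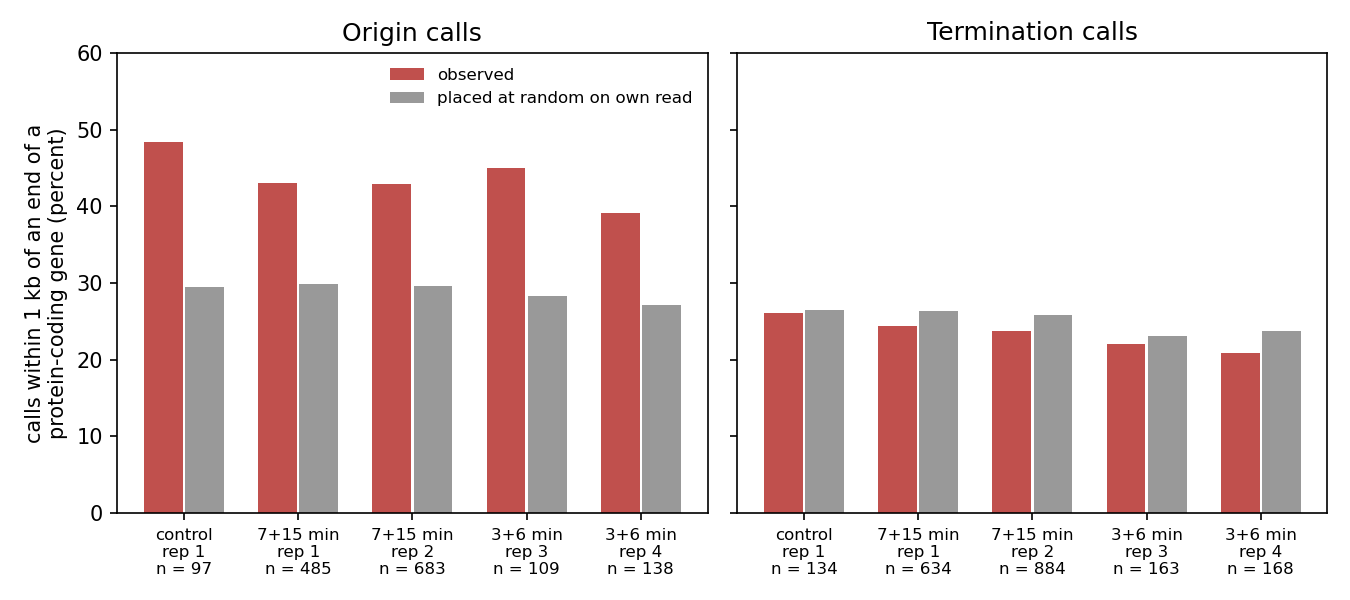
Percent of origin calls (left panel) and of termination calls (right panel) with a midpoint within 1 kb of an end of a protein-coding gene in each untreated library, observed (red bars) and with each call placed at random on its own read (grey bars), with the number of calls under each library. Observed origins average 43.7% against 28.9% at random and exceed random in 5 of 5 libraries, while terminations average 23.4% against 25.1%.

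Origin calls of different libraries met at shared positions. Within 5 kb of 22.5% of the origins of a library lay an origin of another untreated library, against 11.7% after random placement, an excess of 10.9 ± 1.65 percentage points in 5 of 5 libraries (SD over libraries; permutation p = 0.0001, the smallest that the placements can give). The excess was 5.09 points without the 7 and 15 min replicate 1 (permutation p = 0.0002), and 4.96 points with calls up to 5 kb wide alone, a setting chosen after the data were seen. No excess was detected between pulse and gradient origins: 9.59% of pulse origins had a gradient origin within 5 kb, against 9.78% at random (-0.194 ± 0.805 points, permutation p = 0.816). That difference was 0.136 points without the 3 and 6 min replicate 3, and 0.617 points with a distance of 2 kb (permutation p = 0.348).

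Counted in 10 kb tiles over the 5 untreated libraries and the gradient library, 2470 tiles held an origin and 20 held origins of at least 3 libraries, where random placement gave 8.23 (95% range 4 to 13, permutation p = 0.000999, the smallest that 1000 draws can give). The pair with 4 libraries were 2L 14360001 to 14370000, with 6 origins and a mean midpoint 0.225 kb outside spel1, a mismatch repair gene, and 3L 1860001 to 1870000, with 5 origins and a mean midpoint inside HBS1, a ribosome rescue factor (random placement 0.158 such tiles, permutation p = 0.00599). Tiles of 3 pulse libraries had a mean midpoint inside TfIIS, a transcription elongation factor, inside the homeobox gene scro, 0.719 kb from Xrp1, which encodes a DNA-binding protein, 0.997 kb from CG40439, 4.31 kb from the cytochrome P450 gene Cyp6a8 and 13.4 kb from htl, a fibroblast growth factor receptor gene. In the remaining 12 tiles the gradient library was among the 3. Their mean midpoints, which need not be the place of any single origin, lay inside Orc2, a subunit of the origin recognition complex (3R 13960001 to 13970000), inside the Hox gene Ubx (3R 16680001 to 16690000), inside eIF3e, a translation initiation factor subunit, inside kel, and inside CG6425, CG7627, CG5853 and CG43191. In the others the mean midpoint was 0.454 kb from CG8501, 1.07 kb from CG32982, 4.99 kb from CG10874 and 8.54 kb from CG46443.

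No 10 kb tile held terminations of 3 of the 5 untreated libraries. Of 1793 tiles with a termination, 131 had it in 2 libraries. The tile with most calls, 4, lay at X 12700001 to 12710000 inside Smr, a transcriptional corepressor gene of 58.4 kb. Tiles with 3 calls had a mean midpoint inside neb, a kinesin gene (2L 20070001 to 20080000), inside l(2)41Ab (2R 1390001 to 1400000), inside CG31861 and CG31760 (2L 12160001 to 12170000), and 13.2 kb from lt, a vesicle trafficking gene (2L 22950001 to 22960000).

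Gradient origins, from the labelling scheme with stepwise BrdU, lay between genes somewhat more often than positions drawn over each arm, and no such excess was detected near gene ends. Intergenic positions held 35.7% of 1519 gradient origins on the main arms against 32.6% at random, an excess of 3.15 percentage points in 1 library (permutation p = 0.0092, adjusted permutation p = 0.0184), and gene ends held 23.8% against 24.9% (-1.18 points, permutation p = 0.290, adjusted permutation p = 0.290). The difference between pulse and gradient origins near gene ends was not itself tested. Gradient calls had a median width of 2.18 kb, an upper quartile of 8.32 kb and a maximum of 145 kb, and 487 of 1529 were under 100 bp wide. A midpoint therefore need not lie within 1 kb of the true origin, and narrow gradient calls were not tested alone. Read coordinates of this library were not used here, so its random positions spanned each chromosome arm. Calls of this library cluster on reads, with 1529 calls on 1028 reads, and single placement treats them as independent. When the calls of one read were moved together, a setting chosen after the data were seen, the intergenic excess was 3.16 points (permutation p = 0.0314, not adjusted) and the gene-end difference -1.19 points (permutation p = 0.323). When each call was instead moved by at most 20 kb, the intergenic excess was 0.598 points (permutation p = 0.472). With a window of 2 kb the share near gene ends lay 2.81 points below random (-2.81 points, permutation p = 0.0260).

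Of 13 gene lists, long genes alone passed the test. The 307 protein-coding genes of 50 kb or more, with 1 kb on either side, held 195 pulse origins where random placement gave 242 (95% range 225 to 259; permutation p = 0.0001, the smallest that the placements can give; Benjamini-Hochberg adjusted permutation p = 0.0013 over the lists). The deficit depended on the margin, with 179 against 236 for the gene spans alone (adjusted permutation p = 0.0013) and 241 against 266 with 5 kb on either side (adjusted permutation p = 0.0390). Long genes have few gene ends for their length, and the same origins lay near gene ends in excess. The deficit is therefore not independent of the gene-end result. All 5 libraries had origins in them. Per 100 fork midpoints they held 3.01 origins, against 5.12 for all protein-coding genes. The member with most origins was Myo81F, a myosin gene at the base of 3R (567076 to 2532932, 15 origins), followed by Fili (2R 21872030 to 21946259, 5 origins), Sema1a, a semaphorin gene of axon guidance (2L 8542147 to 8672041, 5 origins), and CG40006 (2L 22622417 to 22756349, 4 origins), the first by name of several genes with 4 origins. These counts were not divided by gene length, and Myo81F spans far more DNA than the others named. Gradient origins in long genes numbered 361 against 337 at random, inside the 95% range of 307 to 370 (permutation p = 0.145, adjusted permutation p = 0.933). The difference between pulse and gradient origins in long genes was not itself tested, and their random positions were drawn over reads and over whole arms. Over all 13922 protein-coding genes, pulse origins numbered 1159 against 1144 at random with 1 kb on either side (permutation p = 0.238). The answer depended on the margin, with 963 against 1032 for the gene spans alone (permutation p = 0.0001) and 1328 against 1286 with 5 kb on either side (permutation p = 0.0001).

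The other lists held few origins and did not pass. The 93 ribosomal protein genes had 5 pulse origins against 5.32 at random, the 111 histone genes 2 against 1.57, and the 8 Hox genes 4 against 3.51, of which Ubx held 2 and Antp and Scr 1 each (adjusted permutation p = 1 for each list). Hemocyte and S2 genes had 1 against 1.33, at the phagocytosis receptor gene eater, germline and testis genes 4 against 5.20, chorion genes 0 against 0.113, heat shock genes 1 against 0.658, and tRNA genes 5 against 5.00 (adjusted permutation p = 1 for each list). Germline origins lay inside or within 1 kb of the piRNA pathway genes AGO3, with 3, and aub, with 1. Housekeeping genes had 3 against 1.2 (adjusted permutation p = 0.525), 2 of them at eEF1alpha1, a translation elongation factor, and 1 at the tubulin gene betaTub56D. Neuronal genes had 18 against 21.1 and snRNA and snoRNA genes 8 against 5.09 (adjusted permutation p = 0.659 for both). Replication factors had 3 against 1.16 (adjusted permutation p = 0.525), 1 each at Orc2, at dpa, a helicase subunit, and at geminin, a licensing inhibitor. With 5 kb on either side replication factors held 8 origins against 3.34 (adjusted permutation p = 0.0394) and snRNA and snoRNA genes 32 against 19.7 (adjusted permutation p = 0.0390). None of the 13 lists passed with gradient origins, the lowest adjusted p being 0.933. Over all protein-coding genes with 1 kb on either side, gradient origins numbered 1083 against 1125 with calls placed singly over each arm (permutation p = 0.0141, not adjusted).

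Origins were somewhat more frequent per fork in the windows with most genes, without a steady rise over gene density. Windows of 100 kb with most genes, above 13, held 5.44 ± 0.912 origins per 100 forks (SD, n = 5), and windows with fewest, up to 6, held 4.48 ± 0.760, while those in between held 4.47 ± 1.09. The geometric mean ratio of most over fewest was 1.21, a log2 ratio of 0.28 ± 0.35 (SD, n = 5; permutation of window labels within arms, p = 0.0268). The 3 and 6 min replicate 4 had the opposite direction (-0.31), and without it the log2 ratio was 0.43. Without the 7 and 15 min replicate 1 it was 0.25 (permutation p = 0.0905) and without replicate 2 it was 0.19 (permutation p = 0.192). The result depended on window size: in windows of 50 kb the log2 ratio was 0.66 (permutation p = 0.0001) and in windows of 200 kb it was -0.096 (permutation p = 0.436). Origins per fork on X did not differ from the autosomes beyond the spread between libraries (log2 ratio -0.20 ± 0.61, SD, n = 5; exact sign-flip test, p = 0.5). Without the 3 and 6 min replicate 3 it was -0.39 and without its replicate 4 it was -0.0090.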

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

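The tests of sister forks, random breakage, the chase, fragmentation and fork speed in this part were chosen only after the result was seen, while the tests of the read-end filter and of moving forks were written before theirs. In untreated libraries 190 forks, 0.616% of all, were called on the mitochondrial chromosome, which the comparisons left out, with 13 in the control, 96 and 50 in the 7 and 15 min replicates 1 and 2, and 18 and 13 in the 3 and 6 min replicates 3 and 4. The HU library had 2 of its 26 forks there, 7.69%, against 0.702% in the control, so how many of its other forks are background calls is not known. In the gradient library 10 origins, 0.654% of its calls, lay on that chromosome. The counts of the untreated and gradient libraries stood out because they exceed the limit of 3 that a count of 0 allows in data outside the comparisons, and no explanation was tested. No group held enough samples to test for a library far from the others.

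Lagging-strand tracks were longer than leading-strand tracks over all complete forks (log2 ratio -0.31 ± 0.15, SD, n = 5). A difference in fork rate between the strands would appear between sister forks too, and there the log2 ratio was 0.021, with a 95% interval over libraries of -0.050 to 0.092 that excludes the value over all forks. Sisters can share an EdU boundary at the origin, which can make their tracks alike. Their BrdU segments alone gave 0.014 ± 0.156 (SD, n = 5), from -0.228 to 0.160 over libraries. Removal of short lagging tracks by the filter on read ends would end the difference without the filter, but over all called forks the log2 ratio was still -0.20. Those tracks can be cut at read ends, and unequally. Away from origins and terminations, 31.6% of lagging and 17.0% of leading BrdU ends lay within 20 bp of the read end. The comparison without the filter therefore does not measure how much the filter adds. A candidate explanation that stays open is that lagging molecules of short tracks are lost more often before or during sequencing, since leading molecules made up 62.5% of forks. The design names no group that bears on it, and no biological explanation was tested.

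Reads ended much closer to the BrdU end of a track, the side of the moving fork, than to its EdU end, with medians of 6.31 ± 3.11 kb ahead and 19.2 ± 5.51 kb behind (SD, n = 5). Random breakage of the DNA would give equal distances if the nascent strand ran as far ahead as behind. The highest ratio of the medians over the libraries was 0.530. A strand whose fork was still moving at harvest ends at that fork, so this ratio alone does not argue against random breakage. If reads ended at the fork that was still moving at harvest, faster forks would have both longer BrdU segments and longer distances ahead, and the mean Spearman rho between them over leading tracks was 0.321, from 0.141 to 0.402 over libraries, against 0.103 between EdU length and the distance behind. An added requirement, that rho stay positive without tracks ending within 1 kb of a read end, was met, with 0.259 to 0.481. A chase of 20 min came between the BrdU pulse and harvest, however, so a fork still moving at harvest lay well past the BrdU end, while 45.3% ± 17.9 of read ends lay under 4 kb ahead, against 20.9% ± 5.96 behind (SD, n = 5), and 21.7% within 20 bp ahead against 12.9% behind. Among forks that at their EdU rate would cover at least 8 kb in the chase, the share of ends under 4 kb was higher ahead than behind in every untreated library, by 9.34 to 55.1 percentage points. These were most forks, such as 1180 of 1412 in the control. Their mean shares, 46.3% ahead and 18.8% behind, were near those over all forks, so the subset is no test apart from the pattern that prompted it. Provided that the chase ended labelling and forks kept their rate, which was not measured, the near ends argue against the moving fork as their reason. Why reads end there stays open, and for ends farther ahead the rank correlation alone does not settle it. No biological explanation was tested.

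In the 3 and 6 min replicate 3 the median distance ahead of the BrdU end was 1.31 kb, against 6.49 kb in replicate 4 of the same scheme. More fragmented DNA would shorten the distance behind the EdU end in proportion, and that distance was 1.16 times as long in replicate 3. Slower forks throughout would shorten EdU segments in proportion, and these were 1.01 times as long. A difference in the chase or harvest between these libraries stays possible and was not tested. No biological explanation was tested.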

How the results depend on the processing

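Chosen only after the data were seen were the tests by gene ends, sister forks, gradient calls of one read moved together, all protein-coding genes as a list, caller version, forks with a stall score, BrdU segments, origins with a gap, narrow shared calls, reads without a fork and short reads. Of the alternatives whose test can pass the threshold, 102 kept direction and side of it, 13 reversed, 5 passed it newly and 3 lost it. Exact tests over libraries cannot pass it, so only direction was compared there, and 41 kept it and 4 reversed. Without a test, 18 values stayed within the interval of the main value and 4 moved. The cause was not tested. Left against right forks turned to -0.160 kb at 10 kb from read ends and -0.581 kb on reads of 100 kb or more. The strand difference was 0.021 between sister forks. Origins per 100 forks turned to 0.344 per Mb. Gradient origins at gene ends turned to 0.752 points with shifts of at most 20 kb and reached -2.81 points (permutation p = 0.0260) at 2 kb, while their intergenic excess fell to 0.598 points with shifts. Pulse near gradient origins turned to 0.617 points at 2 kb and 0.0403 with shifts. Gene density turned to -0.096 in 200 kb windows and was 0.66 in 50 kb windows. Terminations at gene ends reached -1.90 points (permutation p = 0.0374) when pooled. With a 5 kb margin origins minus random was 6.27 for ribosomal proteins, 0.888 for hemocyte genes, 0.769 for germline genes (all reversed), 4.66 for replication factors, 12.3 for snRNA and snoRNA genes and 42.3 for all protein-coding genes (all newly past the threshold). With no margin it was -0.918 for histones, -0.290 for tRNA genes, -0.604 for snRNA and snoRNA genes and -69.4 for all protein-coding genes (all reversed). HU over control moved to 0.694 for whole tracks of complete forks and, on reads of 50 kb or less, to 0.479 for BrdU segments, 1.90 for EdU segments and 0.973 for whole tracks.

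Leaving out 1 library at a time gave 0.290 (without the 3 and 6 min replicate 3) to 0.635 kb per min for the fork rate difference, -0.82 to -0.72 for the log2 of BrdU over EdU length per min, 0.269 to 0.444 kb for left minus right, -0.36 to -0.26 for leading over lagging, 3.17 (without the 3 and 6 min replicate 4) to 6.15 points for stall share, and -1.40 to 0.0419 origins per 100 forks (the last without replicate 3). It gave 3.12 to 4.23 points for intergenic origins, 13.8 to 15.5 for origins at gene ends, -0.772 to -0.0810 for intergenic terminations, -1.98 to -1.36 for terminations at gene ends, 5.09 (without the 7 and 15 min replicate 1) to 10.8 for shared origins and -0.363 to 0.136 (without the 3 and 6 min replicate 3) near gradient origins. The log2 ratio by gene density ran from 0.19 (without the 7 and 15 min replicate 2, permutation p = 0.192) to 0.43 (without the 3 and 6 min replicate 4), with 0.25 (permutation p = 0.0905) without the 7 and 15 min replicate 1. The X ratio ran from -0.39 (without replicate 3) to -0.0090 (without replicate 4), sister r from 0.616 to 0.666 and origin distance from 31.8 to 39.2 kb.

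No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Comparisons fixed beforehand for forks with or against transcription, GC content, transcription starts, 3′ ends, exons and introns, with their alternatives, were not run, since strand, exons and sequence were not used here, and shifts of gradient calls could not be kept within reads. Depth limits the HU library (26 forks) and the 3 and 6 min replicate 3 (292 complete forks).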

Other observations

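Apart from distances between origins and counts in gene lists, the values in this part come from tests and summaries chosen only after the data were seen. Forks were sparse on X in every untreated library. Per Mb of arm, X held 0.528 ± 0.0200 of the fork density of the autosomal arms (SD, n = 5), and chromosome 4 held 0.865 ± 0.101. In the 7 and 15 min replicate 2 the densities were 113 forks per Mb on 2L, 106 on 2R, 97.2 on 3L, 100.3 on 3R, 99.7 on 4 and 56.5 on X. No control for DNA copy number was used here, so copy number and replication cannot be separated in these densities.

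Among the Hox genes, counted with 1 kb on either side, Ubx held 2 pulse and 7 gradient origins, while Antp and Scr held 1 pulse origin each and 0 gradient origins.

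Median tracks of complete forks in the long-pulse libraries exceeded those in the short-pulse libraries by 0.370 kb for each of the 13 extra minutes. The pairs of libraries gave 0.209 to 0.531 kb, and all called forks gave 0.435 kb. EdU segments differed by 0.565 kb per extra minute and BrdU segments by 0.306 kb. These values compare different libraries, in which batch, read length and largely the caller version went with the scheme, so they are not a fork rate alone. Origin calls on one read of the gradient library were 9.61 kb apart as median of 499 distances, against 37.5 kb over 30 distances in the untreated pulse libraries. Labelling differed between them, with BrdU raised over 1 hr and a final 30 min against short pulses, and read length bounds both values. They are therefore not a comparison of origin spacing. Within the 7 and 15 min libraries, complete forks called with DNAscent 4.0.3 had medians of 12.7 and 13.2 kb in replicates 1 and 2, and those called with 4.0.1 had 14.8 and 15.9 kb, with the versions in different sequencing output blocks. Over all forks, single blocks of 4.0.1 had medians from 12.0 to 15.5 kb in replicate 1 and from 12.4 to 16.4 kb in replicate 2, ranges that hold the 4.0.3 medians of 12.2 and 13.0 kb, so the gap is not shown to come from the version.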
